A study of Mus musculus with 14 samples.

How the data were processed

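The study measured gene expression in isolated pancreatic islets of 11-week-old mice on a mixed C57BL/6 and NMRI background, per the labels. It has 14 arrays: 5 of control mice, 4 of Pdx-1+/- mice, whose driver allele Pdx-1-tTA makes them haploinsufficient for Pdx-1, and 5 of diabetic IKK2-CApdx-1 mice (here IKK2-CA), which express constitutively active IKK2 through that driver. Total RNA was isolated with RNeasy and labelled with the WT Sense Target method for Affymetrix Mouse Gene 1.0 ST arrays, per the labels. Per the submitters' processing notes, signals were summarised with the robust multichip average (RMA) in Affymetrix Expression Console; its version and settings are not given in the sources used here. The deposited values are log2 signals per transcript cluster, a reading taken from their range and near-equal medians, since the log base is not stated. They compare arrays for the same gene, not genes with each other.

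The labels do not say whether each array is a separate mouse, so arrays may be technical repeats and the p-values measure the spread between samples. Replicate numbers recur in the 3 groups. Correlations between same-number arrays after removing group means did not pair them, so no pairing was used, and a fit with the number as a block is given in the closing section.

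The table has 35556 transcript clusters, of which 23410 are listed in the array's gene table used here. Those with 1 gene symbol (21789) were kept, and those with several (1621) or not listed (12146) were left out of the gene tests; genes such as Ins1, Trp53, Bax and Nfkb1, whose clusters have several symbols or none, were not analysed here. For the 999 genes with several clusters the cluster with the highest mean was kept, which left 19938 genes. No filter on signal and no further normalization was applied. The array medians over these genes lay between 6.45 and 6.55, the highest values between 13.85 and 13.96 and the lowest between 2.16 and 2.29. With arrays, signal over background and the number of arrays limit which changes can be seen.

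Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in 1 fit of 3 group means over all 14 arrays, with 11 residual and 3.46 prior degrees of freedom. Comparisons were IKK2-CA against Pdx-1+/-, IKK2-CA against control and Pdx-1+/- against control. The adjusted p is that of Benjamini and Hochberg over all genes of a comparison, with a threshold of 0.05, and SE is the moderated standard error. Fold is 2 to the power of the log2 difference. The median change of all genes was −0.015, −0.012 and −0.0049 log2 in the 3 comparisons.

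For groups of genes, 26 lists were tested with limma camera at its preset correlation of 0.01, adjusted over the lists of a comparison: NF-κB targets and feedback, chemokines and cytokines, interferon-stimulated genes, antigen processing and MHC class I, MHC class II, complement and acute phase, β-cell transcription factors, glucose sensing and insulin secretion, other islet endocrine cells, genes kept low in β-cells, endocrine progenitor and dedifferentiation genes, endoplasmic reticulum stress, oxidative stress, apoptosis, cell cycle, oxidative phosphorylation, markers of acinar, ductal, myeloid, T and natural killer, B, endothelial, stellate and Schwann cells, heat shock, and sex-linked genes. Beside it stand camera with an estimated correlation, fry, and the members past the threshold over all genes and adjusted over the list alone. The 1 list call that held with an estimated correlation was that of endocrine progenitor genes in IKK2-CA against control.

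The groups, comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names, per comparison, the 12 largest rises and 12 largest falls that passed without overlap between arrays, the genes Pdx1, Ikbkb, Ins2, Gcg, Sst and Ppy, and up to 4 members of each list. Chosen after seeing the data were the fits without Pdx-1+/- array 4 and IKK2-CA array 5, the fits with intestinal and adipocyte scores as covariates, and the lists of 28 intestinal, 25 adipocyte, 26 dendritic cell, 20 B-cell and lymph node, and 23 and 7 β-cell genes.

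The alternatives were array median centring, quantile normalization, eBayes with trend and robust estimation, a fit of only the 2 groups compared, leaving out the lowest 30% of genes by mean, testing every transcript cluster, the mean of a gene's clusters, array weights, the replicate number as a block, an acinar score as a covariate, and leaving out each array in turn. Agreement between comparisons that share a group was set beside 100 simulated sets of unchanged groups, independent lists, and 20 divisions of the shared arrays. The 2 groups of each comparison were also regrouped in 100 of 126 ways. Single arrays far from their group were sought with Dixon's test at the 5% level for the 94 genes and 26 lists of the text. Bounds for the tests of explanations came from 10000 random lists (97.5 percentile) and 10000 bootstrap draws. The bootstrap intervals describe a median over the genes of a list, some of them on a single array. They do not measure the spread between arrays. Genes of a list can vary together, with an estimated correlation of 0.68 for the B-cell markers. Intervals and random-list bounds can therefore be too narrow.

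The pipeline was tested on simulated data with all 19938 genes. Genes shifted by log2 1 were recovered in 89.6%, 97% and 94% of cases in the 3 comparisons, and false calls made up 7.25%, 5.71% and 3.47% of calls. The simulated noise was independent between genes and held no arrays that stand apart. These rates check the code and need not hold for the real arrays. Camera called 5 of 5 shifted lists and 0 of 21 others. Those lists held random genes that varied independently, whereas the estimated correlation was 0.78 for the real MHC class II genes. The simulation therefore does not test the preset correlation of 0.01 on correlated lists. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.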

Results

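Gene expression was measured on 14 arrays of pancreatic islets from 11-week-old mice. There were 5 arrays of control, 4 of Pdx-1+/- and 5 of diabetic IKK2-CApdx-1 mice, here called IKK2-CA. Pdx1 encodes a transcription factor that β-cells need for their identity and for insulin production, and per the labels the driver allele Pdx-1-tTA leaves Pdx-1+/- mice haploinsufficient for it. Ikbkb encodes IKK2, the kinase that switches NF-κB on, and IKK2-CA mice made a permanently active form of it in β-cells under that driver. The hormone genes lay near the top of each array's range, where differences can be understated. Ins2 read 12.64, 12.62 and 12.52 in control, Pdx-1+/- and IKK2-CA islets, Gcg 13.25, 13.13 and 13.14, and Ppy 13.16, 13.03 and 12.90. The highest value of an array was 13.85 to 13.96. The number of arrays limits the precision of every difference below.

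Genes of other tissues set 2 arrays apart. On Pdx-1+/- array 4, Sis, a disaccharidase of the intestinal brush border, read 9.16 against 3.31 to 3.45 on the other arrays of its group, and Fabp2, a fatty-acid binding protein of enterocytes, 9.09 against 3.64 to 3.76. Control array 3 read 6.05 for Sis and 6.58 for Fabp2. Its mean over the 28 intestinal genes (0.369) was the next highest after Pdx-1+/- array 4 (0.991). It stayed in the fits without the 2 arrays, so comparisons with control there still hold an array with intestinal genes. On IKK2-CA array 5, Adipoq, which encodes the adipocyte hormone adiponectin, read 10.60 against 5.40 to 6.71, and Plin1, which coats lipid droplets, 9.34 against 6.25 to 6.40. IKK2-CA array 5 also had the highest mean over the MHC class II genes (1.58 above the mean of the 14 arrays), the interferon-stimulated genes (1.06), the myeloid markers (1.12) and the NF-κB targets (0.82).

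**Figure D1:**
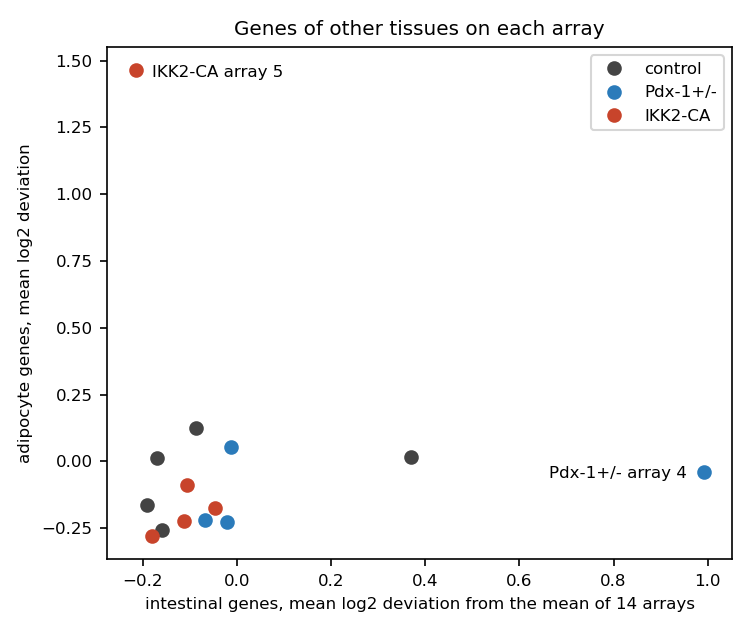
Mean of 28 intestinal genes and of 25 adipocyte genes on each of the 14 arrays, as log2 deviation from the mean of all arrays.

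Ccl17, Ccl22 and Itgax were higher in IKK2-CA islets than in Pdx-1+/- islets. Ccl17 (transcript cluster 10574226), a chemokine that attracts T cells through the receptor CCR4, rose 24.6-fold (log2 4.62, SE 0.45, adjusted p = 0.000963). It went to 10.82 ± 1.04 (SD, n = 5) from 6.20 ± 0.08 (SD, n = 4). Ccl22 (10574213), a ligand of the same receptor, rose 4.68-fold (log2 2.23, SE 0.29, adjusted p = 0.0128), and Ccl5, another T-cell attractant, 3.10-fold (log2 1.63, SE 0.26, adjusted p = 0.0262). Itgax (10557895), which encodes the integrin chain CD11c of dendritic cells and macrophages, rose 4.64-fold (log2 2.21, SE 0.33, adjusted p = 0.0224), to 7.85 ± 0.87 (SD, n = 5) from 5.64 ± 0.17 (SD, n = 4). This comparison asks what active IKK2 changed in mice that carried the same driver allele. The IKK2-CA mice were diabetic, so changes from active IKK2 and changes that followed the diabetes cannot be told apart.

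Itgae, the integrin chain CD103, rose 3.64-fold (log2 1.86, SE 0.28, adjusted p = 0.0237), and Xcr1, a chemokine receptor of conventional dendritic cells, 3.42-fold (log2 1.77, SE 0.28, adjusted p = 0.0266). Fscn1, an actin-bundling protein of mature dendritic cells, rose 3.21-fold (log2 1.68, SE 0.25, adjusted p = 0.0224), and Ccr7, which guides cells to lymph nodes, 3.08-fold (log2 1.62, SE 0.26, adjusted p = 0.0257). Mmp12, the macrophage elastase, rose 4.92-fold (log2 2.30, SE 0.39, adjusted p = 0.0424), Klrb1b, a lectin receptor of natural killer cells, 4.38-fold (log2 2.13, SE 0.25, adjusted p = 0.00567). Cd52, a leukocyte surface glycoprotein, rose 3.91-fold (log2 1.97, SE 0.31, adjusted p = 0.0257) and Gpr141b, an orphan receptor, 4.56-fold (log2 2.19, SE 0.31, adjusted p = 0.0214). The remaining 3 genes, named after their values were seen, were Plbd1 (2.95-fold, SE 0.24), Glipr1 (2.84-fold, SE 0.22) and Adam8 (2.28-fold, SE 0.18). All 15 rose at least 2-fold, and 0 genes fell (limma; 1399 genes had an unadjusted p under 0.05).

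Pdx1 (transcript cluster 10527565) was 7.14 ± 0.21 (SD, n = 4) in Pdx-1+/- islets and 6.67 ± 0.55 (SD, n = 5) in IKK2-CA islets, a log2 difference of −0.47 (SE 0.25, adjusted p = 0.79). Ikbkb (10577560) differed by log2 0.27 (SE 0.11, adjusted p = 0.662). Whether the probes of these genes cover the altered allele or match the transgene is not given in the sources used here, so their levels check nothing about the genotypes. Ins2 (log2 −0.10, SE 0.07, adjusted p = 0.888), Gcg (log2 0.01, adjusted p = 0.997), Sst (log2 −0.22, adjusted p = 0.891) and Ppy (log2 −0.13, adjusted p = 0.976) did not pass.

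Interferon and antigen-presentation genes lay higher as groups. All 33 interferon-stimulated genes were positive (median log2 0.67, camera adjusted p = 3.02e-29, but adjusted p = 0.0882 with an estimated correlation). Of these, 0 rose by limma over all genes and 27 did when adjusted over the list alone. Irf8, a transcription factor also of dendritic cells, was at log2 1.23 (SE 0.27, adjusted p = 0.13) and Ifit1, which binds viral RNA, at 1.19 (SE 0.27, adjusted p = 0.148). The 10 MHC class II genes had a median log2 of 1.05 (camera adjusted p = 1.26e-18, but adjusted p = 0.0882 with an estimated correlation), with 0 past the threshold over all genes and 10 adjusted over the list alone. H2-DMa, which loads peptides, was at log2 1.48 (SE 0.27, adjusted p = 0.0662), and Cd74, the invariant chain, at 1.01 (SE 0.21, adjusted p = 0.101). The 16 genes of MHC class I and antigen processing were all positive (median log2 0.56, camera adjusted p = 1.22e-16, but adjusted p = 0.0882 with an estimated correlation), 0 and 12 of them past the threshold over all genes and adjusted over the list alone. B2m, the light chain, was at log2 0.60 (SE 0.15, adjusted p = 0.235) and Psmb8, an immunoproteasome subunit, at 0.98 (SE 0.25, adjusted p = 0.245).

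Chemokines and NF-κB targets were shifted upward too. Ccl17, Ccl22 and Ccl5 were the 3 of 44 chemokine and cytokine genes that rose, and 14 rose when adjusted over the list alone (median log2 0.24, camera adjusted p = 1.12e-14, but adjusted p = 0.0882 with an estimated correlation). Of the 36 NF-κB targets, 32 were positive and 0 passed over all genes, while 12 rose and 1 fell when adjusted over the list alone (median log2 0.35, camera adjusted p = 6.97e-16, but adjusted p = 0.157 with an estimated correlation). Tnip1, an NF-κB feedback inhibitor, was at log2 0.72 (SE 0.14, adjusted p = 0.0714), and Vcam1, an adhesion molecule that leukocytes bind, at 1.33 (SE 0.33, adjusted p = 0.235). The mean over the NF-κB targets was 0.326 and 0.815 on IKK2-CA arrays 3 and 5, as log2 deviation from the mean of the 14 arrays. It was 0.151 and 0.152 on arrays 1 and 2, and −0.062 on array 4, below Pdx-1+/- arrays 1 and 2 (0.014 and −0.05). Which cells of the islets made these transcripts was not measured.

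Leukocyte and proliferation genes followed the same direction, and all of these lists were highest on IKK2-CA array 5. Itgax was the 1 of 29 macrophage and myeloid genes that rose (7 adjusted over the list alone; median log2 0.33, camera adjusted p = 4.64e-07, but adjusted p = 0.407 with an estimated correlation). Ccl5 was the 1 of 23 T and natural killer cell genes that rose (2 adjusted over the list alone; median log2 0.44, camera adjusted p = 1.06e-13, but adjusted p = 0.157 with an estimated correlation). Of the 17 B-cell genes 16 were positive and 0 passed (median log2 0.16, camera adjusted p = 0.00372, but adjusted p = 0.462 with an estimated correlation). Myeloid and B-cell genes were not called without the 2 arrays that stand apart (adjusted p = 0.0526 and 0.339). Of the 32 cell-cycle genes 29 were positive, 0 passed and 7 rose when adjusted over the list alone (median log2 0.31, camera adjusted p = 8.88e-16, but adjusted p = 0.0882 with an estimated correlation). Mki67, made in dividing cells, was at log2 0.97 (SE 0.24, adjusted p = 0.235), and Kif11, a spindle motor, at 0.76 (SE 0.19, adjusted p = 0.246). The 23 apoptosis genes had a median log2 of 0.20 (camera adjusted p = 7.19e-07, but adjusted p = 0.157 with an estimated correlation) and none passed.

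β-cell genes lay lower as groups, but not on every IKK2-CA array. Of the 23 β-cell transcription factors 22 were negative (median log2 −0.19, camera adjusted p = 0.000294, but adjusted p = 0.407 with an estimated correlation). Of the 39 genes of glucose sensing and insulin secretion 32 were negative (median log2 −0.16, camera adjusted p = 0.000214, but adjusted p = 0.407 with an estimated correlation). None of either list passed. The array means of the lists, as log2 deviation from the mean of all arrays, overlapped between the groups. IKK2-CA array 4 (0.126 for transcription factors, 0.071 for glucose sensing) lay above every Pdx-1+/- array (highest 0.08 and 0.049). The other IKK2-CA arrays (−0.468 to −0.185 and −0.502 to −0.199) lay below every Pdx-1+/- array except array 4 (−0.218 and −0.372). Slc2a2, the glucose transporter of β-cells, was at log2 −0.49 (SE 0.32, adjusted p = 0.872). Endothelial genes (median log2 0.21, camera adjusted p = 0.000241, but adjusted p = 0.407 with an estimated correlation) and stellate genes (0.18, camera adjusted p = 9.72e-05, but adjusted p = 0.407 with an estimated correlation) were called upward. Without the 2 arrays both turned downward and were not called (adjusted p = 0.838 and 0.922). Further upward calls were complement (median log2 0.15, camera adjusted p = 0.00977, but adjusted p = 0.407 with an estimated correlation) and oxidative stress (0.096, camera adjusted p = 0.0123, but adjusted p = 0.241 with an estimated correlation). Others were oxidative phosphorylation (0.062, camera adjusted p = 0.016, but adjusted p = 0.537 with an estimated correlation) and endocrine progenitor genes (0.087, camera adjusted p = 0.0321, but adjusted p = 0.157 with an estimated correlation). Without the 2 arrays complement (adjusted p = 0.589), oxidative stress (0.375) and endocrine progenitor genes (0.258) were not called. In all, 16 of 26 lists were called upward and 2 downward with the preset correlation, and 0 by camera with an estimated correlation or by fry.

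Ccl17 and Klrb1b were the 2 genes whose call held with any array left out (highest adjusted p = 0.0079 and 0.044), and Itgax reached 0.098. Only Ccl17 passed when the 2 groups were fitted alone, and 52 genes passed without the 2 arrays that stand apart, all 15 among them.

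**Figure D2:**
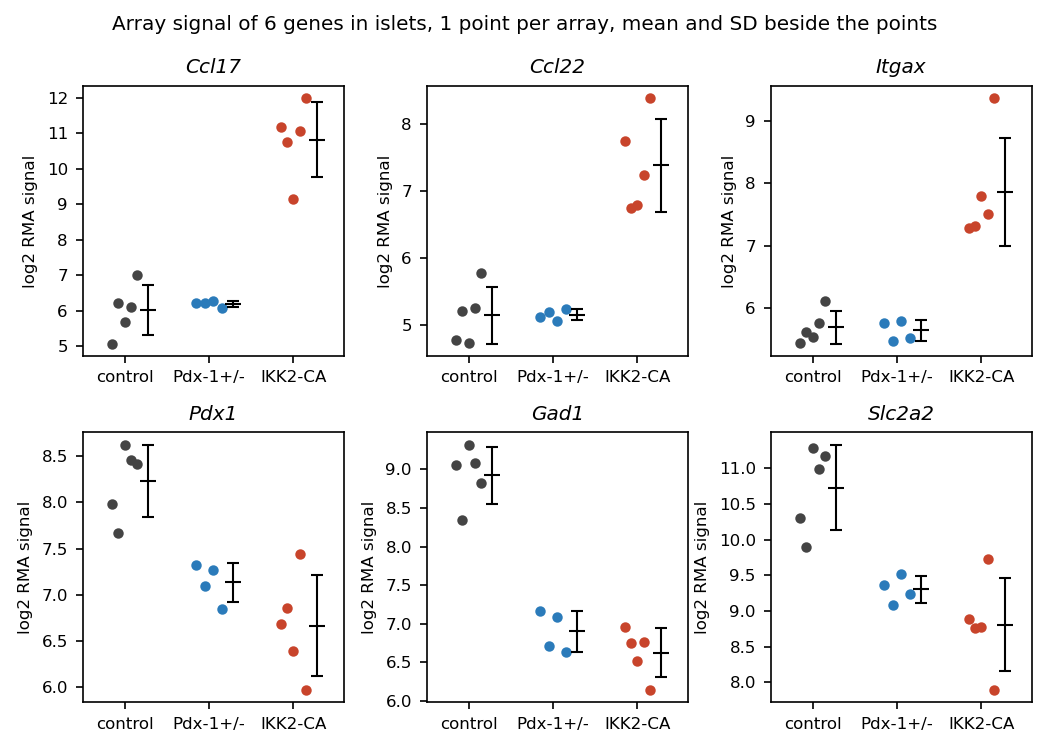
Log2 signal of 6 genes on each array with the mean and SD of each group (n = 4 for Pdx-1+/-, n = 5 for the others).

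Gad1, Slc2a2 and Pdx1 fell in IKK2-CA islets against control islets, while Ccl17 rose. Gad1 (transcript cluster 10472707), which makes the transmitter GABA in β-cells, was 4.93-fold lower (log2 −2.30, SE 0.19, adjusted p = 8.42e-05), at 6.62 ± 0.31 (SD, n = 5) against 8.93 ± 0.37 (SD, n = 5). Slc2a2 (10491171) was 3.79-fold lower (log2 −1.92, SE 0.30, adjusted p = 0.00694), and Pdx1 2.96-fold (log2 −1.56, SE 0.24, adjusted p = 0.0048). Ccl17 rose 27.8-fold (log2 4.80, SE 0.42, adjusted p = 9.29e-05), to 10.82 ± 1.04 (SD, n = 5) from 6.02 ± 0.71 (SD, n = 5). The comparison takes the driver allele, active IKK2 and the diabetes together, and 448 genes passed, 136 up and 312 down, of which 74 and 78 changed at least 2-fold.

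Fam151a had the largest fall. It was 8.77-fold lower (log2 −3.13, SE 0.29, adjusted p = 0.000153) and Tmem215, a membrane protein, 5.97-fold (log2 −2.58, SE 0.26, adjusted p = 2e-04). Sytl4, or granuphilin, which docks insulin granules, was at log2 −2.04 (SE 0.20, adjusted p = 0.000195), Spock1, a proteoglycan, at −2.12 (SE 0.22, adjusted p = 0.00026) and Angptl7, a secreted angiopoietin-like protein, at −2.11 (SE 0.19, adjusted p = 9.29e-05). Npas4, a transcription factor induced by cell activity, was at log2 −1.96 (SE 0.36, adjusted p = 0.0143), and Cntnap2, a neurexin-family adhesion molecule, at −1.74 (SE 0.25, adjusted p = 0.00395). Prss53, a serine protease, was at −1.97 (SE 0.23, adjusted p = 0.000729), Car10 at −1.71 (SE 0.29, adjusted p = 0.00938) and St8sia5, a sialyltransferase, at −1.68 (SE 0.18, adjusted p = 0.000444). Th, which starts catecholamine synthesis, was at log2 −1.49 (SE 0.15, adjusted p = 2e-04).

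Ccl22 rose 4.72-fold (log2 2.24, SE 0.27, adjusted p = 0.00118), Mmp12 4.55-fold (log2 2.19, SE 0.37, adjusted p = 0.00886), and Itgax 4.46-fold (log2 2.16, SE 0.31, adjusted p = 0.00395). Klrb1b rose 3.98-fold (log2 1.99, SE 0.24, adjusted p = 0.000895) and Gpr141b 3.91-fold (log2 1.97, SE 0.29, adjusted p = 0.00451). Madcam1, the addressin of vessels that lymphocytes leave through, rose 4.10-fold (log2 2.04, SE 0.43, adjusted p = 0.0242). H2-M2, a non-classical MHC gene, rose 4.31-fold (log2 2.11, SE 0.45, adjusted p = 0.0267), Ifi209, an interferon-inducible gene, 4.03-fold (log2 2.01, SE 0.42, adjusted p = 0.024) and Dnase1l3, a nuclease, 4.02-fold (log2 2.01, SE 0.35, adjusted p = 0.0114). D17H6S56E-5 rose 4.48-fold (log2 2.16, SE 0.35, adjusted p = 0.00727), and Serpina1c, a protease inhibitor with near-identical copies that the probes may not separate, 4.02-fold (log2 2.01, SE 0.47, adjusted p = 0.0415). The IKK2-CA arrays were split for some of these genes. Arrays 3 and 5 read 8.81 and 8.56 for Madcam1, 8.07 and 8.61 for H2-M2, and 6.81 and 7.55 for Serpina1c. Arrays 1, 2 and 4 read 6.30 to 6.50, 5.74 to 6.20 and 4.64 to 4.75. These were still above every control array (highest 5.57, 5.03 and 3.79).

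Glucose handling and secretion genes fell as a group. Of 39 measured, 12 fell and 0 rose (21 fell and 1 rose adjusted over the list alone; median log2 −0.44, camera adjusted p = 2.71e-13, but adjusted p = 0.178 with an estimated correlation). Ucn3, a hormone of mature β-cells, was at log2 −2.07 (SE 0.48, adjusted p = 0.0407), Ffar1, a fatty-acid receptor, at −1.60 (SE 0.29, adjusted p = 0.014) and G6pc2, a glucose phosphatase, at −1.16 (SE 0.19, adjusted p = 0.00828). Of 23 β-cell transcription factors, Pdx1, Mafa (log2 −1.22, SE 0.23, adjusted p = 0.0172) and Vdr (log2 −0.70, SE 0.16, adjusted p = 0.0402) fell, and 14 did when adjusted over the list alone (median log2 −0.49, camera adjusted p = 5.46e-11, but adjusted p = 0.178 with an estimated correlation). Nkx6-1 was at log2 −0.88 (SE 0.24, adjusted p = 0.0704). Vdr, the vitamin D receptor, is expressed in many cells. Of 15 genes of other islet endocrine cells, Sst, the hormone of δ-cells (log2 −0.67, SE 0.15, adjusted p = 0.0358), and Rbp4, a retinol carrier (log2 −0.76, SE 0.18, adjusted p = 0.0384), fell, with 4 adjusted over the list alone (median log2 −0.21, camera adjusted p = 0.00339, but adjusted p = 0.301 with an estimated correlation). Ins2 was at log2 −0.12 (SE 0.07, adjusted p = 0.425), Gcg at −0.12 (SE 0.09, adjusted p = 0.573), Ppy at −0.26 (SE 0.20, adjusted p = 0.599) and Ikbkb at 0.24 (SE 0.11, adjusted p = 0.283).

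Endocrine progenitor genes rose as the 1 list that held with an estimated correlation. Of 15 measured, 14 were positive and 2 rose (3 adjusted over the list alone; median log2 0.22, camera adjusted p = 4.58e-05, and adjusted p = 0.0312 with an estimated correlation). The 2 were Serpina7, the thyroxine-binding globulin (log2 1.91, SE 0.35, adjusted p = 0.0131), and Cd44, a hyaluronan receptor that leukocytes carry as well (log2 1.03, SE 0.25, adjusted p = 0.0463). Neither directs endocrine fate. Neurog3, the transcription factor that does, was at log2 0.23 (SE 0.18, adjusted p = 0.6). The 20 genes kept low in β-cells had a median log2 of 0.14 (camera adjusted p = 0.00166, but adjusted p = 0.301 with an estimated correlation) and none passed.

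NF-κB targets rose in 5 of 36 cases and fell in 0 (16 adjusted over the list alone; median log2 0.38, camera adjusted p = 3.43e-11, but adjusted p = 0.22 with an estimated correlation). The 4 largest were Vcam1 (log2 1.62, SE 0.31, adjusted p = 0.0162), Tnip3 (log2 0.98, SE 0.24, adjusted p = 0.0448), Nfkbie, an inhibitor that NF-κB induces (log2 0.92, SE 0.22, adjusted p = 0.0438), and Ifngr2, a subunit of the interferon-γ receptor (log2 0.62, SE 0.13, adjusted p = 0.0219). The mean over the NF-κB targets on IKK2-CA array 4 (−0.062) lay below control arrays 1, 2 and 4 (0.081, 0.008 and 0.066). Of 44 chemokine and cytokine genes 7 rose (16 adjusted over the list alone; median log2 0.33, camera adjusted p = 6.62e-11, but adjusted p = 0.178 with an estimated correlation). Among them were Ccl19, a ligand of Ccr7 (log2 1.49, SE 0.24, adjusted p = 0.00715), and Ccl5 (log2 1.44, SE 0.24, adjusted p = 0.00962).

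MHC class II genes rose in 5 of 10 cases (10 adjusted over the list alone; median log2 1.00, camera adjusted p = 2.71e-13, but adjusted p = 0.178 with an estimated correlation). H2-DMa was at log2 1.37 (SE 0.25, adjusted p = 0.014), H2-Ab1 at 1.24 (SE 0.27, adjusted p = 0.0262), H2-Aa at 1.06 (SE 0.24, adjusted p = 0.0345) and Cd74 at 1.02 (SE 0.19, adjusted p = 0.0162). Irf8 (log2 1.09, SE 0.25, adjusted p = 0.0406) was the 1 of 33 interferon-stimulated genes that rose (24 adjusted over the list alone; median log2 0.59, camera adjusted p = 5.27e-16, but adjusted p = 0.178 with an estimated correlation). The 16 genes of MHC class I were all positive, with 0 past the threshold and 12 adjusted over the list alone (median log2 0.42, camera adjusted p = 1.62e-10, but adjusted p = 0.178 with an estimated correlation). Tap1, the peptide transporter, was at 0.89 (SE 0.24, adjusted p = 0.075).

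Macrophage and myeloid genes rose in 3 of 29 cases: Itgax, Ccr2, a monocyte chemokine receptor (log2 1.71, SE 0.36, adjusted p = 0.0251), and Clec7a, a fungal-glucan receptor (log2 1.65, SE 0.29, adjusted p = 0.0111). The list's median log2 was 0.39 (11 adjusted over the list alone; camera adjusted p = 1.61e-09, but adjusted p = 0.301 with an estimated correlation). T and natural killer cell genes (Ccl5 the 1 of 23 that rose, 6 adjusted over the list alone; median log2 0.42, camera adjusted p = 1.62e-10, but adjusted p = 0.22 with an estimated correlation) and B-cell genes (0 of 17; 0.31, camera adjusted p = 3.59e-05, but adjusted p = 0.309 with an estimated correlation) were shifted likewise. IKK2-CA array 5 was the highest of the 14 for each of these leukocyte lists and for NF-κB, interferon and MHC genes. IKK2-CA arrays 1 and 4 lay within the control arrays for T and natural killer cell genes (0.001 and −0.211, against −0.275 to 0.004). For myeloid genes they were at 0.02 and −0.204 (controls −0.504 to −0.02), and for B-cell genes at −0.221 and −0.5 (controls −0.36 to 0.142).

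Cell-cycle genes were shifted upward (median log2 0.28, camera adjusted p = 7.24e-09, but adjusted p = 0.196 with an estimated correlation), with 12 up and 1 down adjusted over the list alone. Their 1 call over all genes went the other way: Ccnd2, a cyclin that β-cells divide with, fell (log2 −0.68, SE 0.15, adjusted p = 0.026). Cell-cycle means on IKK2-CA arrays 1 and 4 (−0.016 and −0.058) lay within those of the control arrays (−0.177 to −0.01). Apoptosis genes had a median log2 of 0.22 (camera adjusted p = 1.44e-06, but adjusted p = 0.178 with an estimated correlation). Casp8, the caspase of death receptors, was at 0.49 (SE 0.12, adjusted p = 0.0513) and the 1 of 23 that rose when adjusted over the list alone. Other upward calls were oxidative phosphorylation (0.10, camera adjusted p = 0.000241, but adjusted p = 0.352 with an estimated correlation), endothelial genes (0.22, camera adjusted p = 0.000378, but adjusted p = 0.354 with an estimated correlation) and acinar genes (0.047, camera adjusted p = 0.018, but adjusted p = 0.593 with an estimated correlation). Stellate genes (0.088, camera adjusted p = 0.0242, but adjusted p = 0.575 with an estimated correlation) and complement (0.034, camera adjusted p = 0.0175, but adjusted p = 0.309 with an estimated correlation) were called as well. Complement and stellate genes were no longer called without the 2 arrays (adjusted p = 0.058 and 0.0747). Outside the called lists, Wfs1, an endoplasmic reticulum protein that β-cells need (log2 −0.56, SE 0.12, adjusted p = 0.025), fell, and Tspan8, a tetraspanin of duct cells (log2 0.54, SE 0.13, adjusted p = 0.0442), rose.

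Leaving out 1 array at a time gave between 120 and 980 genes, and 356 of the 448 also passed without the 2 arrays that stand apart. Gad1, Ccl17, Slc2a2 and Pdx1 held with any array left out (highest adjusted p = 0.00067, 0.00069, 0.028 and 0.02), while calls lost included Mafa (0.061), Ucn3 (0.13), Ffar1 (0.051), Sst (0.12), Vcam1 (0.057), Nfkbie (0.14), Irf8 (0.13), Cd44 (0.13), Madcam1 (0.067), H2-DMa (0.051), H2-Ab1 (0.091), H2-Aa (0.12) and Cd74 (0.053).

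**Figure D3:**
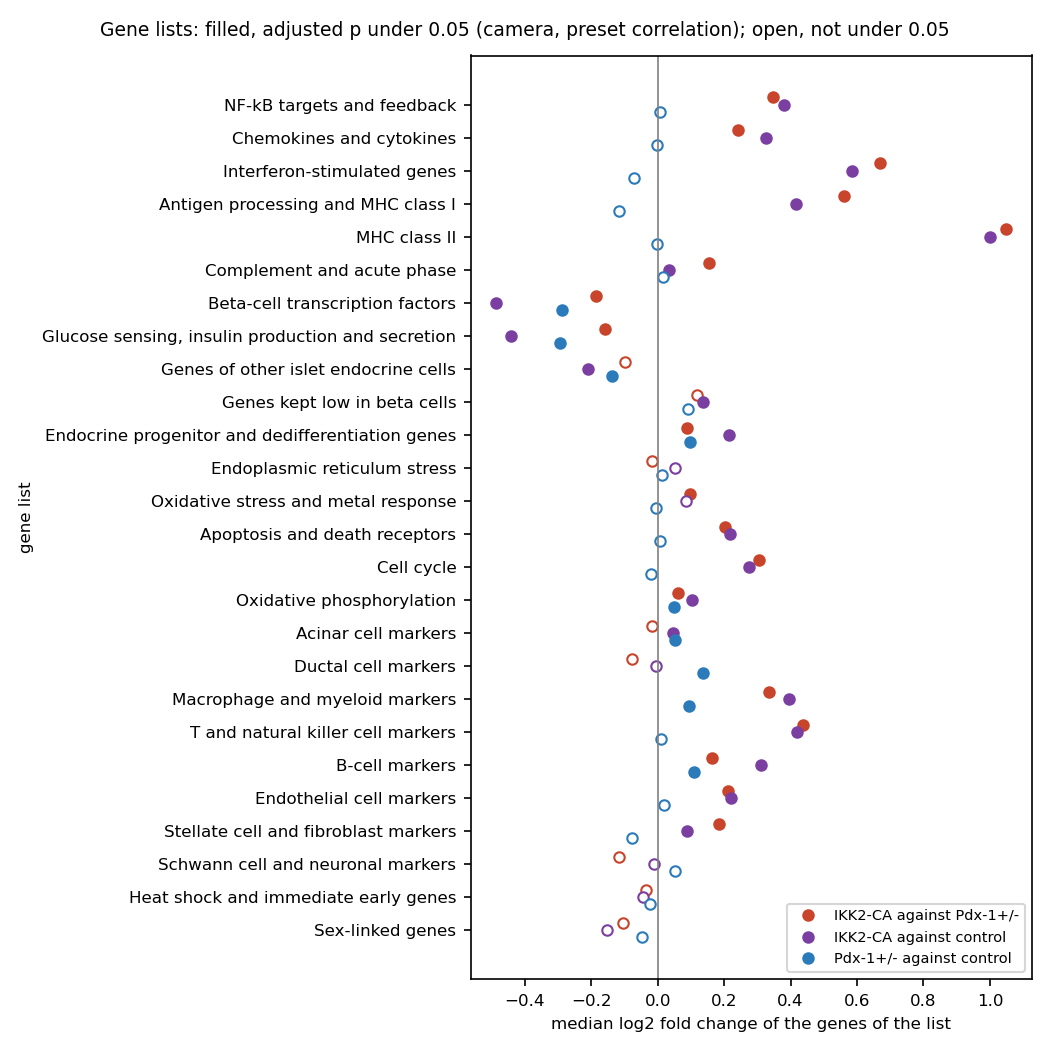
Median log2 fold change of the 26 gene lists in the 3 comparisons, filled where camera with the preset correlation gave an adjusted p under 0.05.

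Gad1, Angptl7 and Tmem215 fell in Pdx-1+/- islets against control islets. Gad1 was 4.07-fold lower (log2 −2.03, SE 0.20, adjusted p = 0.000791), at 6.90 ± 0.27 (SD, n = 4) against 8.93 ± 0.37 (SD, n = 5), and Angptl7 3.88-fold (log2 −1.95, SE 0.20, adjusted p = 0.000791). Tmem215 was 4.65-fold lower (log2 −2.22, SE 0.27, adjusted p = 0.00363), Cntnap2 4.38-fold (log2 −2.13, SE 0.27, adjusted p = 0.00363), Spock1 3.94-fold (log2 −1.98, SE 0.23, adjusted p = 0.00259) and Sytl4 3.15-fold (log2 −1.66, SE 0.21, adjusted p = 0.00363). The comparison asks what the driver allele alone changed.

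Th was 2.33-fold lower (log2 −1.22, SE 0.16, adjusted p = 0.00363). Fam151a was at log2 −2.21 (SE 0.31, adjusted p = 0.00828), Prss53 at −1.71 (SE 0.24, adjusted p = 0.00828), St8sia5 at −1.30 (SE 0.19, adjusted p = 0.0128) and Cyp4f39, a cytochrome P450, at −1.22 (SE 0.19, adjusted p = 0.0147). Cox6a2, a subunit of cytochrome c oxidase, was 2.82-fold lower (SE 0.24, adjusted p = 0.027). In all, 19 genes fell, 14 of them at least 2-fold, and 0 rose (limma; 940 genes had an unadjusted p under 0.05).

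Pdx1 itself was 8.23 ± 0.39 (SD, n = 5) in control and 7.14 ± 0.21 (SD, n = 4) in Pdx-1+/- islets, a 2.14-fold difference (log2 −1.09, SE 0.25, 95% interval −1.63 to −0.56). It did not pass over all genes (adjusted p = 0.21), although the arrays of the 2 groups did not overlap. Mafa (1.99-fold lower, SE 0.25, adjusted p = 0.296) and Slc2a2 (log2 −1.43, SE 0.32, adjusted p = 0.188) did not pass either. Ikbkb was at log2 −0.02 (SE 0.11, adjusted p = 0.999), Ins2 at −0.02 (SE 0.07, adjusted p = 0.999), Gcg at −0.13 (SE 0.09), Ppy at −0.13 (SE 0.21) and Sst at −0.45 (SE 0.16, adjusted p = 0.822).

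Glucose handling genes were shifted downward: Sytl4 was the 1 of 39 that fell, 4 fell adjusted over the list alone, and 34 were negative (median log2 −0.29, camera adjusted p = 7.29e-12, but adjusted p = 0.39 with an estimated correlation). Of the 23 β-cell transcription factors 20 were negative and 2 fell adjusted over the list alone (median log2 −0.29, camera adjusted p = 1.74e-07, but adjusted p = 0.395 with an estimated correlation). Genes of other islet endocrine cells had a median log2 of −0.14 (1 fell adjusted over the list alone; camera adjusted p = 0.0117, but adjusted p = 0.857 with an estimated correlation). The means of the glucose list and of this list were lowest in their group on Pdx-1+/- array 4, which carried the intestinal genes.

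Duct-cell genes were shifted upward, with 2 of 18 up adjusted over the list alone (median log2 0.14, camera adjusted p = 0.000599, but adjusted p = 0.251 with an estimated correlation). Tspan8 was at log2 0.69 (SE 0.14, adjusted p = 0.0957) and Prom1, a membrane protein of duct and stem cells, at 0.51 (SE 0.14, adjusted p = 0.424). Endocrine progenitor genes (1 of 15 up adjusted over the list alone; median log2 0.096, camera adjusted p = 0.00671, but adjusted p = 0.188 with an estimated correlation) held Serpina7 at log2 1.65 (SE 0.37, adjusted p = 0.172). Acinar genes (0.053, camera adjusted p = 0.00103, but adjusted p = 0.945 with an estimated correlation) and myeloid genes (0.093, camera adjusted p = 0.0195, but adjusted p = 0.945 with an estimated correlation) were called upward too. So were B-cell genes (0.11, camera adjusted p = 0.0381, but adjusted p = 0.945 with an estimated correlation) and oxidative phosphorylation (0.050, camera adjusted p = 0.0435, but adjusted p = 0.945 with an estimated correlation). NF-κB targets (median log2 0.0062, adjusted p = 0.828), chemokines (−0.0016, adjusted p = 0.774), interferon-stimulated genes (−0.071, adjusted p = 0.272), MHC class I (−0.12, adjusted p = 0.589) and MHC class II genes (−0.0024, adjusted p = 0.828) were not called.

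Without the 2 arrays, oxidative phosphorylation turned downward and was not called (adjusted p = 0.566), genes of other islet endocrine cells were not called (adjusted p = 0.325), and 12 of the 19 genes still passed. Fam151a, Prss53, St8sia5, Cyp4f39 and Cox6a2 lost their call with some array left out (highest adjusted p = 0.055, 0.052, 0.075, 0.081 and 0.12).

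Gad1, Tmem215, Spock1 and all other 16 genes that fell in Pdx-1+/- islets also fell in IKK2-CA islets against control. These comparisons share the control arrays, and independent lists would share 0.297 falls. Simulated unchanged groups gave 0 shared falls. Hardly any gene passes in such groups, so this 0 was nearly fixed in advance and does not show what shared arrays add. With the control arrays divided between the comparisons, 0 to 20 falls were shared (median 8 of 20 divisions). The fold changes of all genes correlated with r = 0.571, against 0.471 in simulated groups, whose genes varied independently, and 0.33 with divided controls. Ccl17, Itgax and the other 13 genes that rose against Pdx-1+/- islets also rose against control. Here the IKK2-CA arrays are shared: independent lists gave 0.102 shared rises and divided arrays 0 to 25 (median 2). The 0 shared rises in simulation were likewise nearly fixed in advance. The r was 0.775 against 0.472 in simulated groups and 0.473 with divided arrays. Pdx1 passed in IKK2-CA and not in Pdx-1+/- islets against control, but these changes are not shown to differ: their difference is the comparison of IKK2-CA with Pdx-1+/- islets (log2 −0.47, SE 0.25, adjusted p = 0.79).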

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

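In this part no test was chosen after its result was seen: the intestinal and adipocyte tests were written down before they were run. The arrays to test were picked from Sis, Fabp2 and Adipoq. The lists tested hold Lgals4, Fabp4 and Plin1, which stood out on those arrays, so they are not shown to be free of genes already seen. Arrays were compared within their group as the gap to the nearest array over the range of the group (Dixon's test). Over 94 genes and 26 lists in 3 groups, 35 of 360 checks passed, and chance alone gives about 18 (5%). Sis, Fabp2, Lgals4, Adipoq, Fabp4 and Plin1, which are among the 94 because they stood out on single arrays, gave 8 of the 35, so the excess over chance partly repeats what had been seen.

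Sis and Fabp2, both of enterocytes, were far out on Pdx-1+/- array 4 (gap 0.976 and 0.978), as was Lgals4, an intestinal lectin (0.863), and on control array 3 (0.973 and 0.911). The same Pdx-1+/- array was low for Ffar1 (0.857), Wfs1 (0.865) and Plbd1 (0.835), and for the means of the glucose sensing list (0.976) and the other endocrine list (0.926). Adipoq (0.748), Fabp4, a fatty-acid binding protein of adipocytes (0.77), and Plin1 (0.951) were far out on IKK2-CA array 5. That array was also high for Itgax (0.753), Klrb1b (0.847), Plbd1 (0.728), Adam8 (0.722), Bak1, an apoptosis effector (0.936), Casp8 (0.718) and the mean of the apoptosis list (0.763), and low for Mafa (0.75).

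Tissue carried along with the islets is a candidate explanation for these arrays. Over 28 intestinal genes Pdx-1+/- array 4 lay a median log2 0.78 above the other 13 arrays (random lists reach 0.151), while an effect of the genotype is argued against, since Pdx-1+/- arrays 1 to 3 differed from control by 0.022 (interval −0.097 to 0.047, bound 0.39). Control array 3, which carried intestinal genes too, was among the control arrays of that test. Over 25 adipocyte genes IKK2-CA array 5 lay 1.55 above the others (random lists reach 0.0963), and IKK2-CA arrays 1 to 4 differed from Pdx-1+/- arrays 1 to 3 by −0.027 (interval −0.188 to 0.0577, bound 0.775). Islets may express part of these lists too: 8 of the 28 and 12 of the 25 genes lay above the control median of 6.53. This is a rough guide, since the values do not compare genes with each other. None of the genes is in a fixed list. Which tissue was present, and whether the immune genes of IKK2-CA array 5 came with it, stays open.

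Mki67 (0.909), Tmem215 (0.897) and Th (0.912) were high and Vdr (0.88) and H2-Aa (0.878) low on Pdx-1+/- array 3, and Cox6a2 was low on Pdx-1+/- array 1 (0.918). Spock1 was high on IKK2-CA array 4 (0.759), and the heat shock mean low on IKK2-CA array 3 (0.842). Dnase1l3 was low on control array 1 (0.773), Zbtb46, a transcription factor of dendritic cells, high on control array 2 (0.74), and the Y-linked Uty (0.915) and the sex-linked mean (0.772) low on that array. The means of endoplasmic reticulum stress on control array 5 (0.767) and of endothelial genes on control array 4 (0.745) were high. With 4 or 5 arrays a group such gaps arise by chance, and these were not tested further.

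Transcript clusters that name no gene or several genes were left out of the gene tests. Tested separately, 4 passed in IKK2-CA against Pdx-1+/- (3 up, 1 down), 43 in IKK2-CA against control (21 up, 22 down) and 2 in Pdx-1+/- against control (both down). The gene counts leave these changes out, among them the 1 fall in IKK2-CA against Pdx-1+/-, where no gene tested fell, and they are not interpreted here.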

How the results depend on the processing

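In this part, the fits without the 2 arrays that stand apart, the fits with intestinal and adipocyte scores and all regroupings of arrays were chosen only after the results were seen. Differences between settings are given as they came out, and the cause was not tested unless stated.

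Ccl17 and the other 14 genes that rose in IKK2-CA against Pdx-1+/- islets make up a count that moved widely. It was 52 with array weights (39 at least 2-fold), 58 with the acinar score (49 at least 2-fold), 40 with the intestinal and adipocyte scores (29 at least 2-fold) and 52 without the 2 arrays (34 at least 2-fold). With only the 2 groups compared it was 1, Ccl17. Leaving out 1 array gave 2 to 66 genes and 2 to 40 at least 2-fold. It was 2, 2, 2 and 3 without Pdx-1+/- arrays 1, 2, 3 and 4, and the same numbers at least 2-fold, 4 without IKK2-CA array 3 (4 at least 2-fold), 29 without IKK2-CA array 4 (26) and 66 without IKK2-CA array 5 (40). Median centring, quantile normalization, trend and robust variance, dim genes left out, every transcript cluster and the mean of clusters kept it within 1.5 times.

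Gad1, Slc2a2 and the other genes that changed in IKK2-CA against control islets numbered 448. The count was 1431 with array weights, 686 with the acinar score (349 up, 337 down, against 136 and 312) and 241 with only the 2 groups compared. Leaving out 1 array gave 120 to 980 genes and 70 to 264 at least 2-fold, against 152. It was 230, 120, 152 and 190 without control arrays 1, 3, 4 and 5, 178 without IKK2-CA array 3 and 980 without IKK2-CA array 4. At least 2-fold, it was 70 and 91 without control arrays 3 and 4, 100 without IKK2-CA array 3 and 264 without IKK2-CA array 4.

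Gad1, Tmem215 and the other 17 genes that fell in Pdx-1+/- against control islets became 73 calls with array weights (31 at least 2-fold, against 14), 7 of them rises. Leaving out 1 array gave 9 to 48 genes and 7 to 27 at least 2-fold: 48 and 27 without control array 2, 9 and 7 without Pdx-1+/- array 2, and 12 genes without Pdx-1+/- array 3.

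Fitting the replicate number as a replicate block gave 9 genes (9 at least 2-fold) in IKK2-CA against Pdx-1+/-, 197 in IKK2-CA against control and 9 (7 at least 2-fold) in Pdx-1+/- against control. All 9, 189 of 197 and 9 of 9 were calls of the fit without it. The replicate block took the call from 24 named genes and added 1. In IKK2-CA against Pdx-1+/- Mmp12 (adjusted p = 0.138), Ccl5 (0.176), Ccr7 (0.138), Fscn1 (0.0994) and Cd52 (0.0537) no longer passed, nor did Adam8 (0.0788), which is outside the naming rule. Fam151a (0.0709), Sytl4 (0.0637), St8sia5 (0.0717), Cox6a2 (0.0709) and Cyp4f39 (0.0994) did not in Pdx-1+/- against control, and the calls lost in IKK2-CA against control included Ucn3 (0.0956), Sst (0.0688), Irf8 (0.0637), Nfkbie (0.0696), Ccnd2 (0.0699) and Serpina7 (0.0526). With the replicate block, endocrine progenitor genes lost their call in IKK2-CA against Pdx-1+/- (adjusted p = 0.0548), and in Pdx-1+/- against control MHC class II genes (0.0369) and genes kept low in β-cells (0.0333) gained one.

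Regrouping the arrays of 2 groups in 100 of 126 ways asks whether chance can be excluded. For IKK2-CA against control, 1 grouping, the real one, reached 448 genes (highest other 1) and 1 reached 152 at least 2-fold (highest other 0), so chance is argued against. For IKK2-CA against Pdx-1+/-, 2 groupings reached 15 genes, and the highest other called 1036; at least 2-fold, 2 reached 15 and the highest other called 17. So few are not a sign of chance alone, but they show that other divisions of these arrays separate genes as well or better. The grouping with 1036 calls set Pdx-1+/- array 4 and IKK2-CA arrays 1, 2 and 3 against the rest, which points to structure of the samples other than genotype; its cause was not tested. For Pdx-1+/- against control, 3 groupings reached 19 genes (highest other 113) and 3 reached 14 at least 2-fold (highest other 25). The 113 calls came with control arrays 3 and 5 beside Pdx-1+/- arrays 3 and 4, again a structure that the groups do not explain.

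Shared falls of Gad1 and others between Pdx-1+/- and IKK2-CA islets against control went from 19 to 11 at an adjusted p under 0.01 and to 8 (median) with divided controls. Shared rises of Ccl17 and others went from 15 to 2 and to 2.

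NF-κB, interferon and β-cell lists kept their direction with each setting run on lists in both comparisons of IKK2-CA islets, but not their calls. With camera and an estimated correlation, the adjusted p in IKK2-CA against Pdx-1+/- was 0.0882 for chemokines, interferon-stimulated genes, MHC class I, MHC class II and cell cycle. It was 0.157 for NF-κB targets, endocrine progenitor, apoptosis and T and natural killer cell genes, 0.241 for oxidative stress, 0.407 for complement, β-cell transcription factors, glucose sensing, myeloid, endothelial and stellate genes, 0.462 for B-cell genes and 0.537 for oxidative phosphorylation. In IKK2-CA against control it was 0.178 for chemokines, interferon-stimulated genes, MHC class I, MHC class II, β-cell transcription factors, glucose sensing and apoptosis. It was 0.196 for cell cycle, 0.22 for NF-κB targets and T and natural killer cell genes, 0.301 for other endocrine, kept-low and myeloid genes, 0.309 for complement and B-cell genes, 0.352 for oxidative phosphorylation, 0.354 for endothelial, 0.575 for stellate and 0.593 for acinar genes. In Pdx-1+/- against control it was 0.188 for endocrine progenitor, 0.251 for ductal, 0.39 for glucose sensing, 0.395 for β-cell transcription factors, 0.857 for other endocrine genes and 0.945 for oxidative phosphorylation, acinar, myeloid and B-cell genes.

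Fry asks another question than camera: whether a list changed at all, not whether it changed more than other genes. MHC class II, chemokine, β-cell transcription factor, glucose sensing and endocrine progenitor genes passed with fry in IKK2-CA against control. Called by camera but not by fry there were MHC class I (adjusted p = 0.0533), interferon-stimulated genes (0.055), apoptosis and cell cycle (0.0627), NF-κB targets, other endocrine and T and natural killer cell genes (0.075), myeloid (0.143), kept-low and B-cell genes (0.212), oxidative phosphorylation (0.228), endothelial (0.271), complement (0.289), acinar (0.486) and stellate genes (0.538). In IKK2-CA against Pdx-1+/- fry gave 0.0555 for chemokines, interferon-stimulated genes, MHC class I, MHC class II and cell cycle. It gave 0.143 for NF-κB targets, endocrine progenitor, apoptosis and T and natural killer cell genes, 0.29 for oxidative stress, 0.376 for β-cell transcription factors, 0.4 for complement, glucose sensing and myeloid genes, 0.407 for endothelial and stellate genes, 0.509 for B-cell genes and 0.534 for oxidative phosphorylation. In Pdx-1+/- against control it gave 0.319 for glucose sensing, endocrine progenitor and ductal genes, 0.358 for β-cell transcription factors, 0.702 for other endocrine genes and 0.995 for oxidative phosphorylation, acinar, myeloid and B-cell genes.

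Acinar, endothelial and stellate genes turned direction without the 2 arrays that stand apart. In IKK2-CA against Pdx-1+/- acinar genes were then called upward (adjusted p = 0.00342), and endothelial (0.838) and stellate genes (0.922) pointed downward without a call. In Pdx-1+/- against control oxidative phosphorylation pointed downward (0.566) and stellate genes were called upward (0.00967). Calls lost in IKK2-CA against Pdx-1+/- were complement (0.589), endocrine progenitor (0.258), oxidative stress (0.375), myeloid (0.0526) and B-cell genes (0.339), and calls gained were other endocrine genes (0.00644), endoplasmic reticulum stress (0.00677), Schwann (0.0329) and heat shock genes (0.0123). In IKK2-CA against control complement (0.058) and stellate genes (0.0747) were lost, and endoplasmic reticulum stress (0.0159) and ductal genes (0.0261) gained. In Pdx-1+/- against control other endocrine genes (0.325) were lost, and NF-κB targets (0.0464), kept-low genes (0.00366), apoptosis (0.0321), endothelial (0.000492) and heat shock genes (0.00674) gained.

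Acinar genes as a covariate took the call from the acinar list itself (adjusted p = 0.255 in IKK2-CA against control, 0.0828 in Pdx-1+/- against control). The covariate is the mean of that list, so this loss was built in. Acinar genes as a covariate also took the call from oxidative phosphorylation (0.224) in Pdx-1+/- against control. They added oxidative stress (0.0241) in IKK2-CA against control, and kept-low genes (0.00455), apoptosis (0.0487) and endothelial genes (0.00455) in Pdx-1+/- against control. Leaving out the lowest 30% of genes added oxidative stress (0.0288) in IKK2-CA against control and kept-low genes (0.0269) in Pdx-1+/- against control. Median centring took oxidative phosphorylation (0.0539) and B-cell genes (0.0683) from Pdx-1+/- against control. Signs that turned in lists never called are not counted here.

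Pdx1 passed in Pdx-1+/- against control with array weights (log2 −1.13, adjusted p = 0.0121), and in no other setting; Ikbkb passed in none. Of 74 calls of named genes, 35 held with any array left out and 39 did not. The 2 groups alone lost 31 calls, the fit without the 2 arrays 4, trend and robust variance 3, and the tissue scores 2. No named gene turned direction and kept a call. The number of arrays and the signal over background limit the precision of all of these.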

Other observations

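In this part the comparisons with lymph node genes and with β-cell and other endocrine genes were chosen only after the results were seen, and the test of the array with adipocyte genes before.

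Acinar and sex-linked genes gave a view of the preparations. Cpa1, a digestive enzyme of acinar cells, read 13.64, 13.67 and 13.67 in control, Pdx-1+/- and IKK2-CA islets, near the top of the range in every group. Exocrine cells were part of each preparation. Xist, made from the inactive X of females, was low (3.81, 3.85 and 3.80), and the Y-linked Kdm5d (7.33, 7.20 and 7.05) and Uty (7.99, 7.82 and 7.66) were expressed in all 3 groups. The 4 sex-linked genes were not called in any comparison (median log2 −0.11, −0.15 and −0.048; adjusted p = 0.211, 0.177 and 0.774).

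Ductal genes were at a median log2 of −0.077 in IKK2-CA against Pdx-1+/- (adjusted p = 0.198), Schwann cell genes at −0.12 (0.158), acinar genes at −0.018 (0.708), other endocrine genes at −0.098 (0.251), kept-low genes at 0.12 (0.0692) and heat shock genes at −0.034 (0.935). Without the 2 arrays that stand apart, acinar genes turned upward and were called (adjusted p = 0.00342), and other endocrine (0.00644), Schwann cell (0.0329) and heat shock genes (0.0123) were called too. In IKK2-CA against control oxidative stress genes were at 0.086 (0.0577), endoplasmic reticulum stress genes at 0.051 (0.202) and Schwann cell genes at −0.012 (0.389), a list in which Th fell in both comparisons with control. In Pdx-1+/- against control the values were 0.090 for kept-low genes (0.0517), 0.013 for endoplasmic reticulum stress (0.774), −0.0059 for oxidative stress (0.919), 0.0079 for apoptosis (0.443), −0.020 for cell cycle (0.443), 0.0086 for T and natural killer cell genes (0.774), 0.020 for endothelial (0.58) and −0.078 for stellate genes (0.356). Without the 2 arrays endoplasmic reticulum stress (0.0159) gained a call in IKK2-CA against control, and kept-low genes (0.00366), apoptosis (0.0321), endothelial (0.000492) and stellate genes (0.00967, turned upward) in Pdx-1+/- against control.

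Median, mean and test differed in sign for 9 lists, none of them called. They were endoplasmic reticulum stress in IKK2-CA against Pdx-1+/- (median −0.018, mean 0.034, adjusted p = 0.356), ductal (−0.0054, 0.075, 0.0655) and heat shock genes (−0.045, −0.0082, 0.808, test upward) in IKK2-CA against control, and 6 in Pdx-1+/- against control. Those were NF-κB targets (0.0062, −0.018, 0.828), chemokines (−0.0016, −0.0092, 0.774, test upward), MHC class II (−0.0024, −0.0052, 0.828, test upward), complement (0.015, −0.024, 0.828), Schwann (0.051, −0.048, 0.919) and heat shock genes (−0.023, −0.00026, 0.774, test upward).

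Dendritic cells in or around the islets of IKK2-CA mice are a candidate explanation for Itgax, Itgae, Xcr1 and Ccr7: 24 of 26 further dendritic cell genes were higher than in Pdx-1+/- islets (median log2 0.48), 0 passed singly and none is in a fixed list. Of the 26, 14 lie above the control median, a rank among probes of different genes and not a measure of expression. The array with adipocyte genes alone is argued against, since the median was 0.307 without the 2 arrays (random lists reach 0.0717). Lymph node tissue as the source in every array was not decided. In IKK2-CA arrays 1 and 4 dendritic cell genes were at 0.32 and 0.326. The 20 B-cell and lymph node genes, 16 of them in fixed lists, were at −0.126 (interval −0.303 to 0.101) and −0.40 (−0.53 to −0.22). Taken alone, these 2 arrays argue against lymph node tissue with its B cells. Yet Madcam1 (6.45 and 6.30) and Ccl19 (8.54 and 8.82), named for their rise, were higher there than on any Pdx-1+/- array (highest 5.40 and 8.01). In arrays 2, 3 and 5 dendritic cell genes were at 0.322, 0.46 and 1.01, and the B-cell and lymph node genes were also up, at 0.182, 0.615 and 0.944. Lymph node tissue as part of the difference stays open, with these genes at 0.165 over all arrays (0.11 to 0.281, bound 0.239). Batf3 (log2 0.12, adjusted p = 0.903) and Zbtb46 (log2 0.00, adjusted p = 0.998), transcription factors of dendritic cells, did not differ, and whether cell number or cell state changed was not tested.

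Against control, 5 of the 26 dendritic cell genes rose in IKK2-CA islets (median log2 0.54), and the B-cell and lymph node genes were at 0.33. These lists were at 0.046 and 0.14 in Pdx-1+/- against control. Intestinal genes were at −0.32, −0.014 and 0.25 in the 3 comparisons and adipocyte genes at 0.27, 0.23 and −0.035. Without the 2 arrays they were at −0.00063, −0.020 and 0.022, and at −0.027, −0.063 and −0.087. Ms4a1 (log2 0.13, adjusted p = 0.992) and Cd79a (log2 0.28, adjusted p = 0.965), both of B cells, did not pass between IKK2-CA and Pdx-1+/- islets. The IKK2-CA arrays were split for Ms4a1: arrays 2, 3 and 5 read 6.19, 6.87 and 7.2, and arrays 1 and 4 read 4.83 and 4.89. The Pdx-1+/- arrays read 5.28 to 6.60.

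Fewer β-cells in the Pdx-1+/- preparations could lower β-cell genes such as Gad1 together: 7 genes mostly of β-cells had a median log2 of −1.09, 1 of them past the threshold, and 6 of the 7 are in a fixed list. Pdx1, for which these mice are haploinsufficient, is 1 of the 7 and sets that median. Its fall may follow from the genotype alone, so the median says little on the β-cell share. The other 6 were at −0.559 (Nkx6-1) to −2.03 (Gad1), and Pdx1 also stayed in the mean subtracted below. After subtraction of each array's mean over the 7 genes 3 still differed, Gad1 (−0.86, adjusted p = 0.00059), Nkx6-1 (0.60, adjusted p = 0.00047) and G6pc2 (0.37, adjusted p = 0.035), but without Gad1, whose own fall lowers that mean, 1 of 6 did, Nkx6-1 (0.46, adjusted p = 0.0024). Dilution of all islet cells was not decided. Genes of other endocrine cells were at −0.040 without the 2 arrays (interval −0.179 to 0.169, bound −0.275), which taken alone argues against it. In the test as first run, with all arrays, they were at −0.139 (−0.333 to −0.0823, bound −0.303), which decided nothing. The list also holds Sst, which read 12.58 in control islets, near the top of the range, where falls can be understated. Dilution, a smaller share of β-cells, as the whole cause or part of it, and a direct effect of Pdx-1 dose on Gad1 stay open.

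The test of the β-cell share was run before on 23 β-cell genes, of which 12 differed after subtraction (9 of 22 without Gad1). It was replaced since other islet cells express some of these genes, so that they need not fall alike. Of the 23, 3 fell in Pdx-1+/- against control (median log2 −0.605), 20 of the 23 lie above the control median, again only a rank among probes, and 19 are in a fixed list. In IKK2-CA against control 13 of the 23 genes fell (median log2 −1.10) and 6 of the 7 (−1.56, the value of Pdx1 itself). Against Pdx-1+/- islets the medians were −0.30 and −0.37, with none past the threshold.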
